A study of Mus musculus with 32 samples.

How the data were processed

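The libraries were made from total RNA of ascending aorta with a stranded messenger RNA kit and sequenced in 2 batches, per the labels' protocols. Base calls were converted with bcl2fastq, reads were checked with FastQC, aligned with STAR to the mouse genome build GRCm39 and quantified with RSEM, per the submitters' processing notes, which state no program versions. The deposited values used here are the counts of STAR's splice junction tables for each library, which hold for each intron the count of uniquely mapped reads that cross it and the count of multi-mapped reads that cross it. Each table gives the intron's position, its strand and whether the aligner's own annotation held it. No normalisation had been applied to these counts, per the file headers and labels. Gene-level RSEM values were not analysed here.

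Genes were recognised as follows. The plan made before the data were examined was to match introns to an annotation by exact position, but the annotation at hand (GENCODE release M21) is on build GRCm38, and the files are on GRCm39. No position was converted between builds. A gene was recognised where the lengths of its successive introns and of the exons between them recurred in the same order and strand among the junctions of the files, which needs no shared coordinate. Of 26585 annotated genes with at least 2 introns, 18009 were recognised by such a chain and 3295 genes more, among them genes with a single intron, by their place between recognised neighbours, giving 21304. In a control with the junction positions mirrored, 1107 genes (4.16%) found a chain. Recognised genes lay in step with a recognised neighbour in 99.6% of cases with 4 or more introns, 98.6% with 3 and 97.1% with 2. Uniquely mapped reads on junctions assigned to 1 gene made up 97.5% of 374927292 reads on 541273 junctions, reads on junctions shared by genes 1.32% and reads on junctions that could not be named 1.17%. All positions printed are those of the files.

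The count of a gene was the sum of its uniquely mapped junction reads over the introns assigned to that gene alone. A read that crosses more than 1 intron counts once for each, and a gene without introns has no count. Multi-mapped reads were left out, so genes with near-identical copies are under-counted and uncertain: among those named, Saa2, C4b, Naip2, Oas1a, H2-M2 and Igkv3-12. Strand was taken from the junction, so antisense genes were kept apart.

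Counts were scaled by the trimmed mean of M values (TMM), genes were kept by edgeR's filterByExpr, and all 32 libraries were fitted at once with edgeR's robust quasi-likelihood model with a term for each group and a term for the sequencing batch. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Group A, B and HI labels were used as given, and the replicate number was not used as a pair, since the closest library of another group had the same number in only 4 of 32 libraries. This count uses the numbers of the titles, which for 2w-A run from 1 to 6 where the library names run from 2 to 7. All group B and 1w-A libraries were in batch 1 and all 2w libraries in batch 2, so the batch term rests on 1w-HI alone, with 4 libraries in batch 1 and 3 in batch 2. Log2 fold changes between 1w-HI and 1w-A or B therefore rest on its 4 batch 1 libraries. Those between 2w-HI and 1w-HI rest on its 3 batch 2 libraries. Means and direction counts cover all libraries of a group. Across batches, values from a fit without this term are therefore also given for most values printed that differ by more than 1.5-fold or change a call, and are the values given first for 2w-A and 2w-HI against B. Levels are CPM (uniquely mapped junction reads divided by the scaled library size), as mean ± SD over the libraries of a group, and log2 fold changes are given ± SE. Direction counts ("lower in 6 of 6") give the libraries of the first group on that side of the median of the second.

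The genes named were set by a rule fixed in advance: the inflammasome genes Gsdmd, Casp1, Casp4, Nlrp3, Il1b and Il18 always; for A against HI at each time the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 50 reads per library in the higher group; for the other comparisons 4 and 4; up to 4 members of each list described, by smallest adjusted p; for the difference between times the 5 smallest adjusted p in each direction; and 5 genes for junction usage. Some genes that this rule picked and some cassette exons that the tests called are not described here. The 35 gene lists, also fixed in advance, were: contractile smooth muscle, fibrillar collagen and its processing, elastic fibre, matricellular and repair matrix, matrix proteases and inhibitors, inflammasome and pyroptosis, necroptosis and apoptosis, markers of neutrophils, of macrophages and monocytes, of dendritic cells and antigen presentation, of T and NK cells, of B and plasma cells, of thymus, of endothelium, of lymphatic endothelium, of adventitial fibroblasts, of cardiomyocytes, of skeletal muscle, of white and of brown adipocytes, of nerve and Schwann cells, of mesothelium, of erythroid cells and of sex, and proliferation, chemokines and cytokines, interferon response, NF-kB and immediate response, TGF-beta signalling, complement and coagulation, mitochondrial oxidative phosphorylation, glycolysis and hypoxia, osteochondrogenic genes, heritable thoracic aortic disease genes, and the unfolded protein and heat shock response. The 34 lists with at least 5 tested members were tested as sets with limma's camera on voom values, with a preset correlation of 0.01 between genes and again with an estimated correlation. Some genes stand in more than 1 list. Choices not called fixed in advance or before the data were examined were made later and are named as such where they appear.

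Junction usage within genes was tested with edgeR's diffSpliceDGE on annotated junctions, with Simes p values per gene. The inclusion of a cassette exon was the mean of its 2 inclusion junctions divided by the sum of that mean and the skipping junction, in events of 15 genes fixed in advance with a mean of at least 20 reads in each group compared and a mean inclusion from 0.05 to 0.95, and was compared with 2-sided exact permutation tests. The share of junction reads on introns absent from the aligner's annotation was compared in the same way. For a gene with 0 reads in a group the fold is a lower bound against 3 reads over that group, and with 1 to 3 reads the ratio of pooled CPM is given with its 95% counting interval. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers.

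The tests of genes, lists, junction usage and cassette exons were run first on simulated counts. For genes, 200 were changed by known folds, with the means, dispersions and library sizes of the real libraries. Each gene was drawn independently, without outlying animals or a batch effect. The shares below describe such counts and need not hold for the real libraries. In the comparison of 1w-A with 1w-HI, 44.8% of the genes changed 1.5-fold, 61.2% of those changed 2-fold and 87.9% of those changed 4-fold were recovered, with 11 of 13026 unchanged genes called. For 2w-A against 2w-HI the recovered shares were 50.7%, 68.7% and 84.8%, with 3 of 13037 unchanged genes called, and for 2w-A against 1w-A they were 19.4%, 46.3% and 71.2%. The calls of each comparison were recounted in 100 splits of its libraries into groups of the same sizes (40 for junction usage, and all 35 for the batches of 1w-HI), the real split included. Tools were edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3 with the data.table package (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.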

Results

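Reads that cross exon junctions were counted in 32 libraries of mouse ascending aorta, which fall by their labels into 5 groups: B (6 libraries), 1w-A (6), 1w-HI (7), 2w-A (6) and 2w-HI (7). The series describes dissected and control aortas collected on days 7 and 14, and aortas of naive mice as a baseline, with 6 animals per group. The 7 libraries each of 1w-HI and 2w-HI differ from that number without a stated reason, and all were kept. B is the only group without a time point and is taken as that baseline, 1w as day 7 and 2w as day 14. The labels do not state whether A or HI is the dissected arm, and give no genotype, so the groups keep their labels here. Each library held 9662698 to 14239741 uniquely mapped junction reads, with 10360925 to 12768321 in B, 11266602 to 14239741 in 1w-A, 10916835 to 13482336 in 1w-HI, 10967431 to 13331953 in 2w-A and 9662698 to 12032165 in 2w-HI. Genes detected averaged 15160 ± 192 (SD, n = 6) in B, 16137 ± 355 (n = 6) in 1w-A, 16032 ± 272 (n = 7) in 1w-HI, 16002 ± 280 (n = 6) in 2w-A and 15676 ± 128.999 (n = 7) in 2w-HI. The 10 most-read genes held 11.6% ± 0.713 of the reads in B and 22.1% ± 2.45 in 1w-A. The first principal component of the 13372 genes tested held 58.5% of the variance and the second 8.72%.

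**Figure D1:**
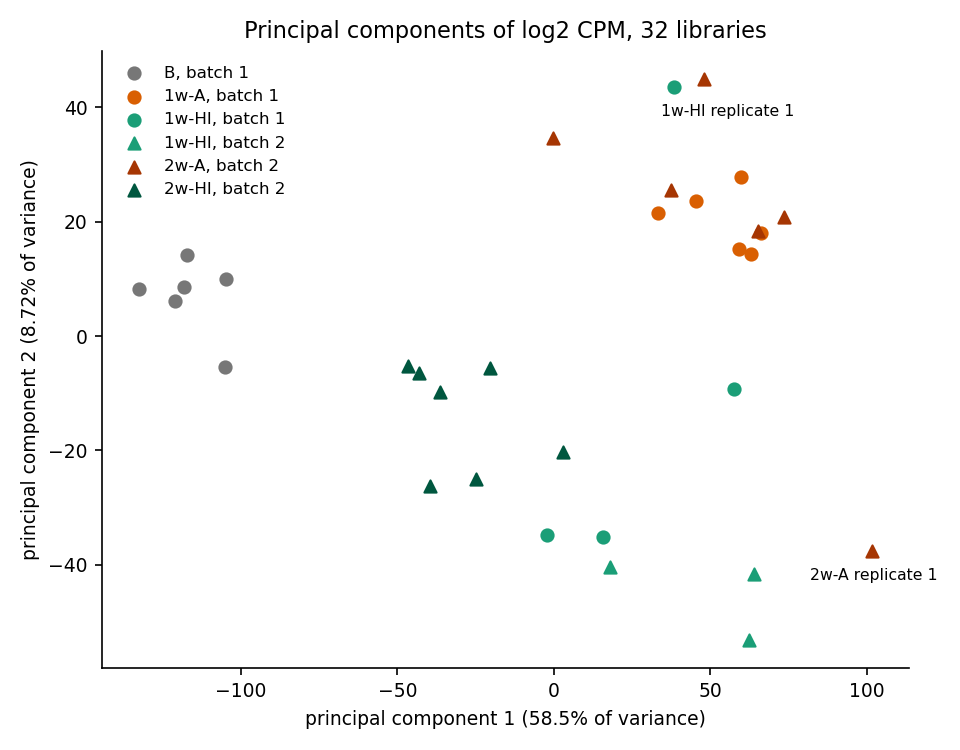
Scores of the 32 libraries on principal components 1 and 2 of log2 CPM, in arbitrary units, coloured by group with circles for batch 1 and triangles for batch 2. Component 1 held 58.5% of the variance and parted B from the other groups, 1w-HI replicate 1 lay beside the A libraries, and 2w-A replicate 1 lay apart from the other 5 libraries of its group.

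Gsdmd encodes gasdermin D, the pore-forming protein named in the series title, and was read in every library. Its introns lie on chromosome 15 from 75734331 to 75738845 on the plus strand of GRCm39. Gsdmd stood at 13.7 ± 1.46 CPM (SD, n = 6) in B, 66.9 ± 12.5 (n = 6) in 1w-A, 70.2 ± 13.2 (n = 7) in 1w-HI, 72.4 ± 27.8 (n = 6) in 2w-A and 48.4 ± 4.94 (n = 7) in 2w-HI. Every library held Gsdmd reads, with 421 or more in each library outside B. Casp1 and Casp4, whose proteases cleave gasdermin D, stood in B at 2.99 ± 0.855 and 9.85 ± 1.44 CPM, in 1w-A at 34.4 ± 11.2 and 36.8 ± 8.31, and in 1w-HI at 33.1 ± 7.91 and 53.3 ± 16.2. At 2w they stood at 38.8 ± 16.3 and 43.7 ± 24.3 CPM in A and at 20.9 ± 5.12 and 26.1 ± 3.47 in HI. The sensor gene Nlrp3 and the cytokine gene Il1b varied far more between animals: in 1w-HI they ranged from 4.55 to 76.1 CPM and from 8.20 to 979 CPM. Il18, a cytokine gene of the same pathway, stood at 1.80 ± 0.701 CPM in B and at 8.79 ± 1.85 in 1w-A.

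**Figure D2:**
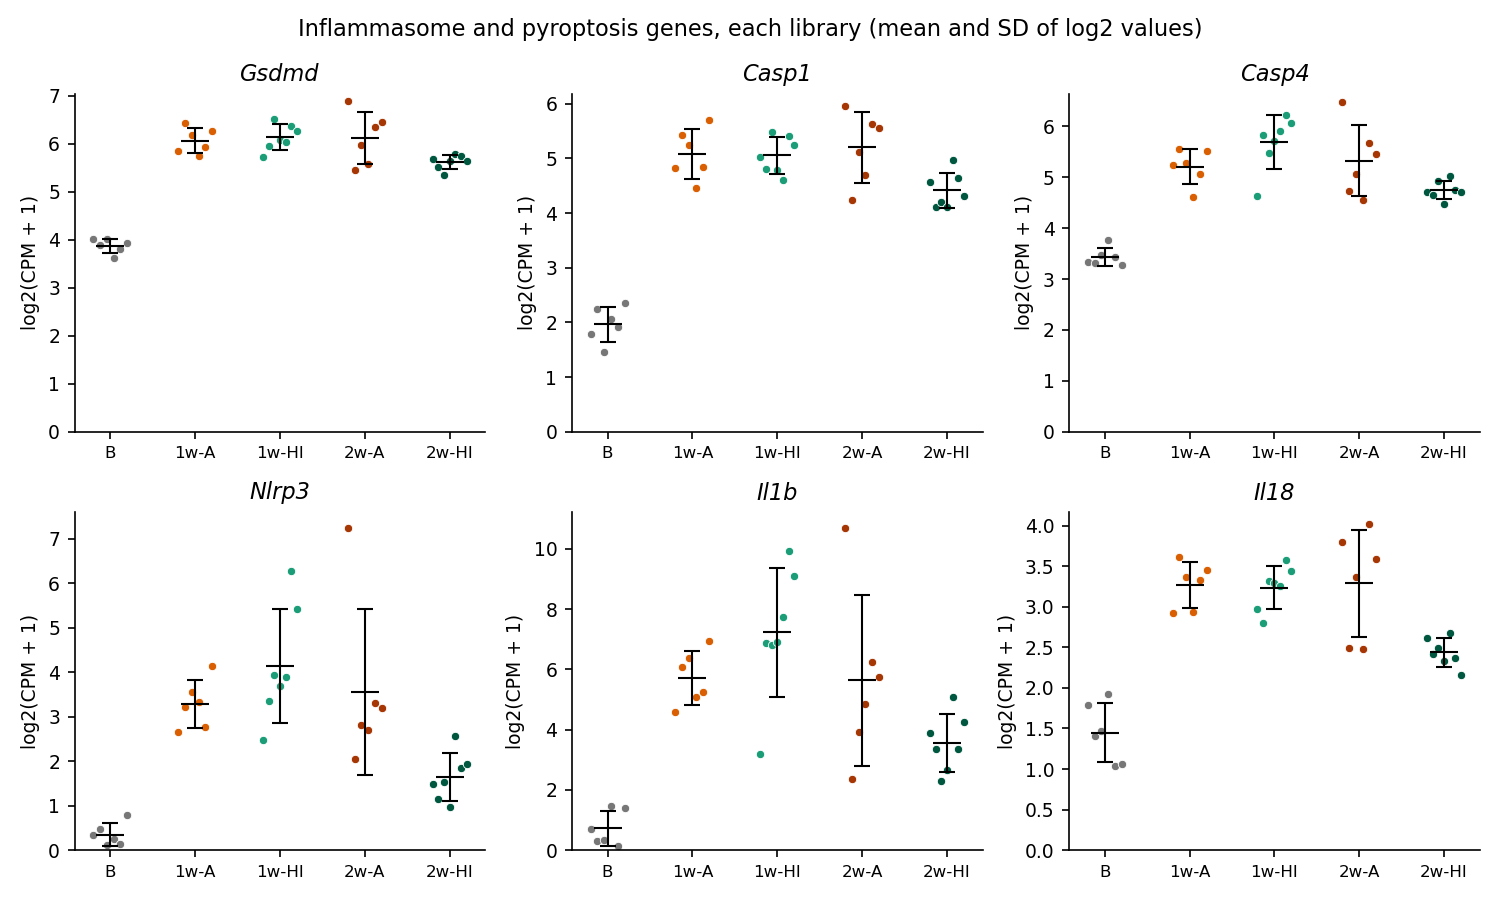
Levels of Gsdmd, Casp1, Casp4, Nlrp3, Il1b and Il18 as log2 of CPM plus 1, with a point per library and bars at the mean and SD of each of the 5 groups. Gsdmd lay between 11.2 and 15.1 CPM in the B libraries and at 39.7 CPM or more in every other library.

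At day 7, 1w-A and 1w-HI were compared to ask what separated the arms early. With the batch term, the log2 fold changes compare 1w-A with the 4 1w-HI libraries of batch 1, while the CPM means cover all 7. Genes of the smooth muscle contractile apparatus were lower in 1w-A. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14013049 to 14109139), fell from 3825 ± 2014 CPM (SD, n = 7) in 1w-HI to 1016 ± 433 (n = 6) in 1w-A, a log2 fold change of -1.94 ± 0.37 (SE, adjusted p = 0.00527, lower in 6 of 6 libraries). Acta2, smooth muscle actin (chromosome 19, 34219211 to 34232689), fell by 1.19 ± 0.31 log2 units (adjusted p = 0.0257, lower in 6 of 6). Tcap, which encodes a sarcomeric cap protein, stood at 3.33 ± 1.77 against 40.4 ± 30.01 CPM, a log2 fold change of -3.69 ± 0.56 (adjusted p = 0.00155, lower in 6 of 6). The clock output gene Dbp and the clock gene Per2 fell by 2.52 ± 0.46 and 2.39 ± 0.40 log2 units, each lower in 6 of 6 libraries (adjusted p = 0.00357 and 0.00182). Vwc2, a secreted BMP inhibitor, and Trim58, a ubiquitin ligase of erythroid cells, fell by 3.44 ± 0.53 and 3.27 ± 0.52 (adjusted p = 0.00155 and 0.00182), also in 6 of 6. Other large falls were 2210407C18Rik (-2.70 ± 0.46) and Ppp1r1b, a phosphatase inhibitor (-2.57 ± 0.59). Cartilage collagens were among the largest rises, each higher in 6 of 6. Col9a1 stood at 44.8 ± 26.6 against 3.42 ± 1.09 CPM, a log2 fold change of 3.75 ± 0.57 (adjusted p = 0.00155), and Col2a1, the main cartilage collagen (chromosome 15, 97874068 to 97902289), at 956 ± 821 against 29.5 ± 56.4 CPM, a log2 fold change of 4.35 ± 1.21 (adjusted p = 0.0367). The remaining large rises, the airway secretory gene Bpifb1 and the motile cilium genes Dnah5, Cfap43 and Dnah10 with Prom1 and Cdhr4, came from 1w-A replicate 6, where Bpifb1 stood at 880 CPM against a mean of 7.42 in the other 5. Without that library their log2 fold changes fell to 3.81 for Bpifb1 (adjusted p = 0.195) and to between 1.12 and 1.34 for the other 5 genes (adjusted p from 0.265 to 0.599).

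Across the lists, the contractile list had the most members called at 1w. Of 25 measured, 17 fell and 0 rose (19 and 1 adjusted over the list alone), led by Myh11, Synpo2, which binds actin (-1.84 ± 0.36), Pcp4l1 (-1.92 ± 0.40) and Mylk, the myosin light chain kinase (-1.29 ± 0.28), each lower in 6 of 6 libraries. The contractile falls numbered 18 without 1w-HI replicate 1 or 3, 10 without 1w-A replicate 3, 2 without 1w-HI replicate 4 and 0 without 1w-HI replicate 2. The groups overlapped in the mean log2 CPM of this list. It was 6.62 in 1w-A replicate 1, and 6.60, 6.60 and 6.61 in 1w-HI replicates 1, 3 and 7. Repair matrix genes moved the other way. Of 22 matricellular genes 6 rose and 0 fell (10 and 0 adjusted over the list alone), among them the thrombospondin genes Thbs1 (2.00 ± 0.49) and Thbs4 (1.83 ± 0.48), Aspn (1.05 ± 0.26) and the tenascin gene Tnc (0.86 ± 0.23). Of 30 collagen genes 4 rose and 1 fell (12 and 1 adjusted over the list alone), with Col12a1, a fibril-associated collagen, at 2.02 ± 0.43, Col6a3 at 0.68 ± 0.17, Col8a2 at 1.99 ± 0.57 and the processing enhancer Pcolce2 at -0.89 ± 0.20. The collagen rises numbered 12 without 1w-HI replicate 3 and 0 without 1w-HI replicate 2 or 4. Of 12 osteochondrogenic genes, Col2a1 and the aggrecan gene Acan (1.47 ± 0.44) rose and 0 fell (4 and 0 adjusted over the list alone). In this list 0 rose without 1w-A replicate 3 or 4 or 1w-HI replicate 2, 3 or 4, and 4 rose without 1w-HI replicate 1. Of 19 complement and coagulation genes 3 fell, with C7 at -1.52 ± 0.39 and C1ra at -0.55 ± 0.14 (4 adjusted over the list alone). Of 24 heritable aortic disease genes Myh11, Mylk, Acta2 and Flna, an actin crosslinker (-1.14 ± 0.22), fell (5 fell and 4 rose adjusted over the list alone). A single member fell in the elastic fibre list of 17 (Fbln1, -0.83 ± 0.17; 2 fell and 4 rose adjusted over the list alone), the protease list of 29 (the stromelysin gene Mmp3, -2.37 ± 0.51), the macrophage list of 30 (the engulfment receptor gene Mertk, -0.59 ± 0.15) and the brown adipocyte list of 9 (Prdm16, -1.09 ± 0.32). Of 11 nerve genes 1 rose (5 rose and 1 fell adjusted over the list alone), and of 17 adventitial fibroblast genes Fap rose (0.84 ± 0.25) and Pi16 fell (-1.06 ± 0.28).

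Most immune lists had no member past the threshold at day 7. None of the 28 inflammasome, 18 necroptosis, 18 neutrophil, 15 dendritic cell, 22 T and NK cell, 11 B cell, 32 proliferation, 30 chemokine, 24 interferon or 20 NF-kB genes measured passed edgeR's adjusted p over all genes or over the list alone. Nor did any of the 7 thymus, 20 endothelial, 8 lymphatic, 15 cardiomyocyte, 7 skeletal muscle, 15 white adipocyte, 10 mesothelial, 7 erythroid, 22 TGF-beta, 28 mitochondrial, 24 glycolysis, 16 unfolded protein or 4 sex-linked genes over all genes (adjusted over the list alone 1 skeletal muscle gene rose and 1 fell, and 1 unfolded protein gene rose). Gsdmd differed by -0.01 ± 0.19 log2 units (adjusted p = 0.989, 3 libraries higher and 3 lower), Casp1 by 0.09 ± 0.28, Casp4 by -0.25 ± 0.26, Nlrp3 by -0.10 ± 0.75, Il1b by -0.56 ± 0.98 and Il18 by 0.20 ± 0.27 (adjusted p from 0.673 to 0.968). Without the batch term Nlrp3 stood at -1.39 (adjusted p = 0.216) and Il1b at -2.31 (adjusted p = 0.122). The sign of Gsdmd changed with the scaling: the log2 fold change was 0.01 with DESeq2.

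Of the 606 genes called between the arms at 1w, 501 were lower in 1w-A and the others higher (2484 at an unadjusted p under 0.05). DESeq2 called 270 higher and 599 lower. With a 2-fold minimum 50 rose and 247 fell. These calls rested on few animals. Without 1w-HI replicate 2, 4 genes rose and 12 fell, 32 of the 38 called genes named for this comparison lost their call (Myh11 -1.57, adjusted p = 0.0876) and 0 contractile or matricellular genes passed. Without 1w-HI replicate 4, 8 rose and 89 fell and 28 of the 38 lost it. Without 1w-A replicate 3 or 5 the counts were 49 and 255 or 66 and 328, and without 1w-HI replicate 1 or 3 they were 269 and 649 or 248 and 805. Col9a1, Tcap, Vwc2, Trim58, Dbp and Per2 passed whichever library was left out. Within batch 1 alone 636 genes were called, 472 of them shared. That fit compares the same libraries as the main log2 fold changes, so it is no independent check. Without a batch term 1421 genes were called, 590 of them shared, with Col2a1 at 5.01 and Thbs1 at 1.37. With only these groups fitted 3 genes passed, with the most-read junction of each gene 271, and with the replicate number as a block 14 higher and 88 lower. With camera, 11 lists were called higher and 2 lower, of which none held with an estimated correlation (contractile list, adjusted p = 0.377 with an estimated correlation), and the same is true of the camera calls of the other comparisons.

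**Figure D3:**
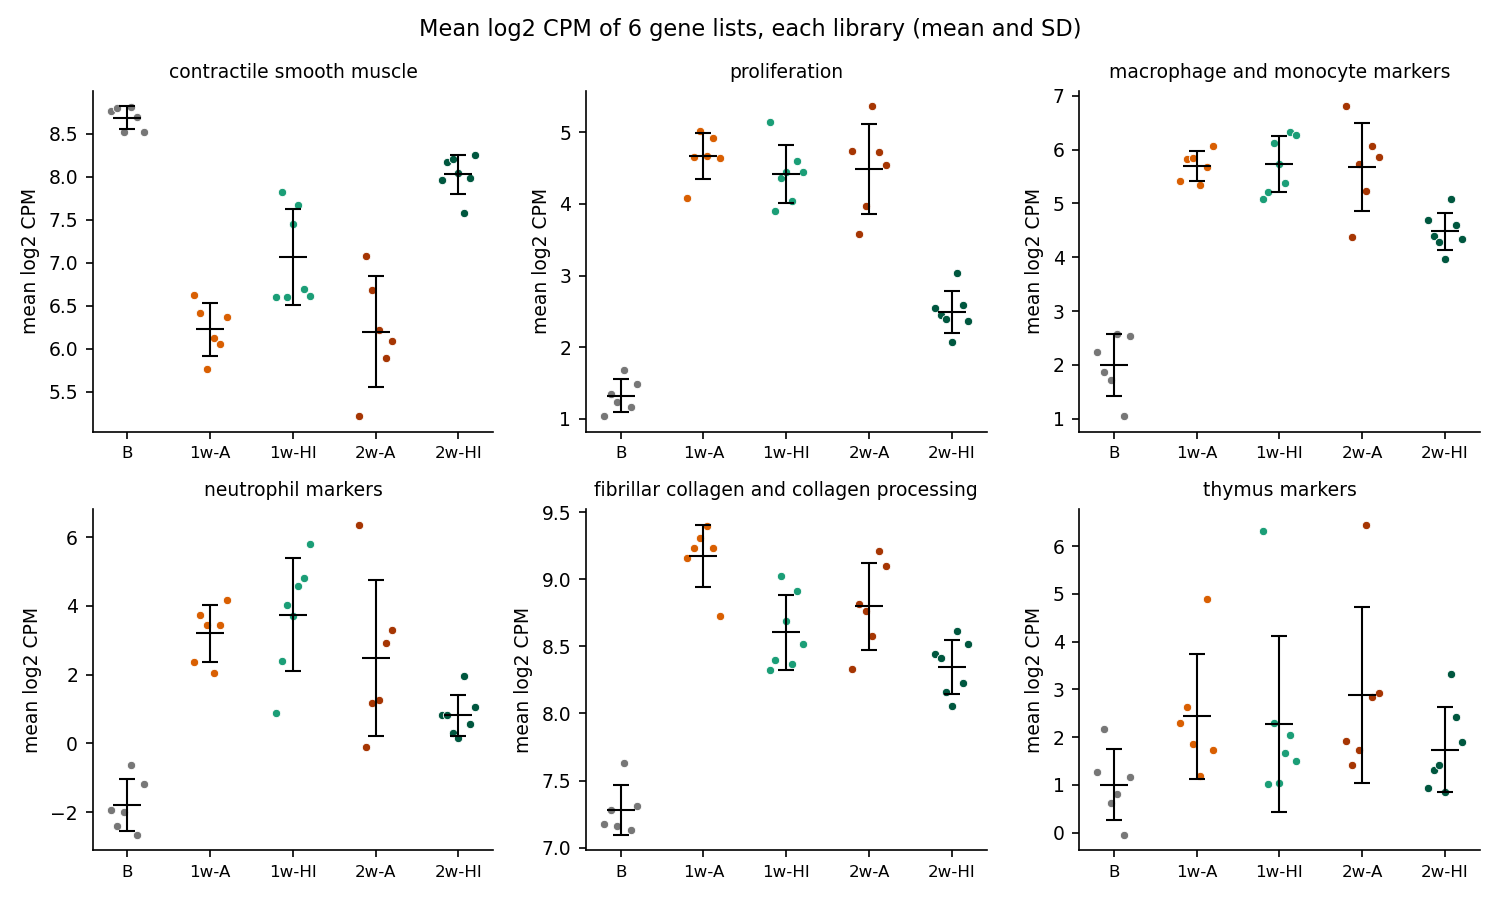
Mean log2 CPM of the members of 6 gene lists, with a point per library and bars at the mean and SD of each of the 5 groups. The 2w-HI libraries lay at 7.58 or higher on the contractile list, and 1w-HI replicate 1 (6.32) and 2w-A replicate 4 (6.46) stood above the rest of their groups on the thymus list.

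At day 14 the same question was asked of 2w-A and 2w-HI, and the arms differed far more widely. Myh11 fell from 9094 ± 1733 CPM (SD, n = 7) in 2w-HI to 1401 ± 814 (n = 6) in 2w-A, a log2 fold change of -2.70 ± 0.35 (SE, adjusted p = 1.13e-06, lower in 6 of 6 libraries). Acta2 fell from 14420 ± 2618 to 3638 ± 1689 CPM, a log2 fold change of -1.99 ± 0.29 (adjusted p = 3.86e-06, lower in 6 of 6). The largest falls included the atrial and cardiac muscle genes Myl7 (-7.27 ± 1.31), Myh6 (-6.28 ± 1.48) and Actc1 (-5.53 ± 1.08), each highest in 2w-HI replicate 6, with 258 CPM of Myh6 against a mean of 49.7 in the other 6 libraries. Without it the log2 fold change of Myh6 was -5.58 (adjusted p = 0.0025). Tcap (-3.70 ± 0.50), Ppp1r1b (-3.69 ± 0.56), the calcium channel subunit gene Cacna2d3 (-3.41 ± 0.37) and Vwc2 (-3.29 ± 0.47) fell in 6 of 6. Genes of hypertrophic cartilage and bone were among the largest rises: Col10a1, a collagen of hypertrophic chondrocytes (chromosome 10, 34266040 to 34270183), stood at 58.6 ± 30.8 against 0.417 ± 0.638 CPM, a log2 fold change of 7.13 ± 1.15 (adjusted p = 1.87e-05, higher in 5 of 6). The bone sialoprotein gene Ibsp (6.60 ± 1.12) and Col2a1 (5.99 ± 1.05) rose in 5 of 6 each. Without 2w-A replicate 5, Ibsp rose by 5.82 (adjusted p = 0.000122). The keratin genes Krt5 (7.98 ± 2.06) and Krt17 (6.85 ± 1.77) and the thymic protease gene Prss16 (9.02 ± 2.29) were highest in 2w-A replicate 4, without which they stood at 6.45, 5.08 and 4.69, with Prss16 no longer past the threshold (adjusted p = 0.0869). Arg1, an arginase of activated macrophages, and U90926 were driven by 2w-A replicate 1. Arg1 fell from a log2 fold change of 6.78 ± 1.53 to 1.34 without it (adjusted p = 0.294). U90926, with 1 read in all of 2w-HI, stood 361-fold higher (95% counting interval 64.4 to 14310) and at a log2 fold change of 2.16 without that library (adjusted p = 0.248).

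Inflammation and cell division were higher in 2w-A. All 32 proliferation genes rose, 0 fell and the count was the same over the list alone, with the mitotic kinesin gene Kif20a at 29.9 ± 9.16 against 4.18 ± 1.20 CPM, a log2 fold change of 2.84 ± 0.23 (adjusted p = 2.1e-09), and Tk1 (2.10 ± 0.19), Tpx2 (2.27 ± 0.23) and Kif2c (2.98 ± 0.31) beside it, each higher in 6 of 6 libraries. All 24 interferon response genes rose as well, among them the chemokine gene Cxcl10 (3.97 ± 0.47) and the transcription factor genes Irf7 (2.90 ± 0.39) and Irf9 (0.91 ± 0.12) with Oasl2 (1.95 ± 0.27). Of 30 chemokine and cytokine genes 27 rose and 0 fell (28 and 1 adjusted over the list alone), including Cxcl14 (3.76 ± 0.48), Ccl12 (2.70 ± 0.40) and the monocyte attractant gene Ccl2 (2.29 ± 0.37). Macrophage genes rose in 21 of 30 and fell in 1 (22 and 2 adjusted over the list alone), led by the Fc receptor gene Fcgr1 at 59.7 ± 39.5 against 6.18 ± 1.60 CPM, a log2 fold change of 3.27 ± 0.35 (adjusted p = 7.74e-08, 6 of 6), Ccr2 (2.43 ± 0.36), C1qa (1.43 ± 0.22) and C1qc (1.40 ± 0.23). Antigen presentation genes rose in 12 of 15, with the class II regulator gene Ciita at 2.15 ± 0.34 and H2-DMa at 1.31 ± 0.22. T and NK cell genes rose in 19 of 22 (21 adjusted over the list alone), with the cytotoxic granule genes Gzma (2.93 ± 0.58) and Nkg7 (1.83 ± 0.38), but in 8 without 2w-A replicate 4. Thymus genes rose in 7 of 7, but in 2 without any of 2w-HI replicates 1 to 4, in 3 without 2w-HI replicate 7 and in 1 without 2w-A replicate 4, where the T cell factor gene Tcf7 fell from 2.72 ± 0.97 to 0.61 (adjusted p = 0.5681). Neutrophil genes rose in 15 of 18 but in 7 without 2w-A replicate 1. The collagenase gene Mmp8 stood at 4.55 ± 1.00, Lcn2, a secreted iron-binding protein, at 3.75 ± 0.83 and the receptor gene Trem1 at 4.92 ± 1.10, and without that library at 1.46 (adjusted p = 0.0859), 1.46 (adjusted p = 0.0437) and 2.35 (adjusted p = 0.0346). B cell genes rose in 2 of 11 (1 adjusted over the list alone, and 1 without 2w-A replicate 1 or 2w-HI replicate 2, 4 or 7).

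Most inflammasome genes measured rose in 2w-A. Of 28, 22 rose and 0 fell (23 and 0 adjusted over the list alone), beside 3725 rises among all 13372 genes, and 17 rose without 2w-A replicate 1. Il18bp, which encodes the inhibitor of interleukin 18, rose by 1.95 ± 0.31 log2 units (adjusted p = 1.34e-05), the caspase gene Casp8 by 0.93 ± 0.16 and Naip2, a bacterial sensor gene with near-identical copies, by 2.17 ± 0.40, each in 6 of 6 libraries. Naip2 stood at 1.41 without 2w-A replicate 1. Gsdmd rose by 0.58 ± 0.17 (adjusted p = 0.00519, higher in 4 of 6) and Casp1 by 0.90 ± 0.24 (adjusted p = 0.0028, 5 of 6). Il18 rose by 1.11 ± 0.24 (adjusted p = 0.000344, 6 of 6). Nlrp3 rose by 3.71 ± 0.72 (adjusted p = 0.000128, 6 of 6), and by 1.48 (adjusted p = 0.00491) without 2w-A replicate 1, which held 150 CPM against a mean of 6.34 in the other 5. Il1b rose by 4.53 ± 0.97 (adjusted p = 0.000351, 5 of 6), but by 1.42 (adjusted p = 0.0618) without that library, and Casp4 by 0.74 ± 0.23 (adjusted p = 0.00783, 5 of 6), but by 0.44 (adjusted p = 0.0618) without it. Necroptosis genes rose in 13 of 18, with the kinase gene Ripk3 at 1.79 ± 0.26 and the nucleic acid sensor gene Zbp1 at 2.62 ± 0.39.

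Vessel wall genes changed in both directions. Contractile genes fell in 22 of 25 and rose in 1, and the falls numbered 22 whichever library was left out. Among them Actg2 (-2.51 ± 0.27), Pcp4l1 (-3.02 ± 0.38), Synpo2 (-2.57 ± 0.32) and Mylk (-1.92 ± 0.25) were lower in 6 of 6 libraries. Flna, of the heritable aortic disease list, stood at -1.76 ± 0.20, also lower in 6 of 6. Collagen genes rose in 14 of 30 and fell in 6 (14 and 7 adjusted over the list alone): Col12a1 stood at 786 ± 400 against 62.8 ± 23.4 CPM, a log2 fold change of 3.64 ± 0.38 (adjusted p = 5.59e-08, 6 of 6), Col11a1 at 3.98 ± 0.63 and Pcolce2 at -1.33 ± 0.18. Matricellular genes rose in 12 of 22 and fell in 2. Thbs1 stood at 1604 ± 556 against 74.3 ± 30.01 CPM, a log2 fold change of 4.43 ± 0.44 (adjusted p = 4.2e-08, 6 of 6), Tnc at 1.60 ± 0.19, fibronectin (Fn1) at 1.33 ± 0.19 and decorin (Dcn) at -1.09 ± 0.13. Elastic fibre genes rose in 5 of 17 (3 without 2w-A replicate 5 or 2w-HI replicate 3, 4 or 6) and fell in 7, among them Fbln1 (-1.64 ± 0.16), Mfap4 (-1.58 ± 0.20) and the latent TGF-beta binding gene Ltbp4 (-1.48 ± 0.27). Proteases and inhibitors rose in 13 of 29 and fell in 4 (14 and 6 adjusted over the list alone), and rose in 7 without 2w-A replicate 1. Adam12 rose by 2.95 ± 0.33 and the collagenase gene Mmp13 by 5.65 ± 0.72, or by 4.93 without 2w-A replicate 5. Osteochondrogenic genes rose in 7 of 12 and fell in 1 (8 and 1 adjusted over the list alone), with Runx1 at 1.88 ± 0.22 and Acan at 2.45 ± 0.37. Adventitial fibroblast genes fell in 12 of 17 and rose in 3 (1 without 2w-A replicate 5), with Clec3b (-1.82 ± 0.22), Dpt (-1.37 ± 0.17) and Pi16 (-1.93 ± 0.25). Complement and coagulation genes rose in 7 of 19 and fell in 3 (8 and 3 adjusted over the list alone), with C7 at -3.02 ± 0.37.

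Genes of other cell types also moved. Endothelial genes rose in 16 of 20, among them the junction gene Cdh5 (1.15 ± 0.25) and Ptprb (1.01 ± 0.22), and white adipocyte genes in 11 of 15, with Adipoq at 1.39 ± 0.33. Cardiomyocyte genes fell in 13 of 15 (9 without 2w-HI replicate 6), mesothelial genes in 4 of 10 (5 fell and 1 rose adjusted over the list alone), with Upk3b at -2.83 ± 0.66 and Msln at -2.58 ± 0.63. Skeletal muscle genes fell in 4 of 7 and rose in 1, nerve genes fell in 5 of 11 and rose in 1, and heritable aortic disease genes fell in 8 of 24 and rose in 5. NF-kB genes rose in 11 of 20 and fell in 4, glycolysis genes rose in 10 of 24 and fell in 3 (6 and 6 without 2w-A replicate 1), unfolded protein genes rose in 5 of 16 and fell in 6, and TGF-beta genes rose in 3 of 22 and fell in 5. Mitochondrial genes rose in 3 of 28, or 0 adjusted over the list alone, and in 7 without 2w-HI replicate 4 and 1 without any of 2w-A replicates 2, 3 and 4 and 2w-HI replicates 1, 2, 5 and 7. TGF-beta genes rose in 5 without 2w-A replicate 2. A single lymphatic gene of 8 and brown adipocyte gene of 9 fell, and 0 of 7 erythroid genes passed. Of 4 sex-linked genes 1 rose, but 0 rose and 1 fell without 2w-A replicate 1. In total 3725 genes were called higher and 3212 lower in 2w-A, and 1557 and 902 with a 2-fold minimum. The count ranged from 6182 to 7285 genes when each library was left out in turn. With camera 11 lists were called higher and 3 lower, of which none held with an estimated correlation.

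**Figure D4:**
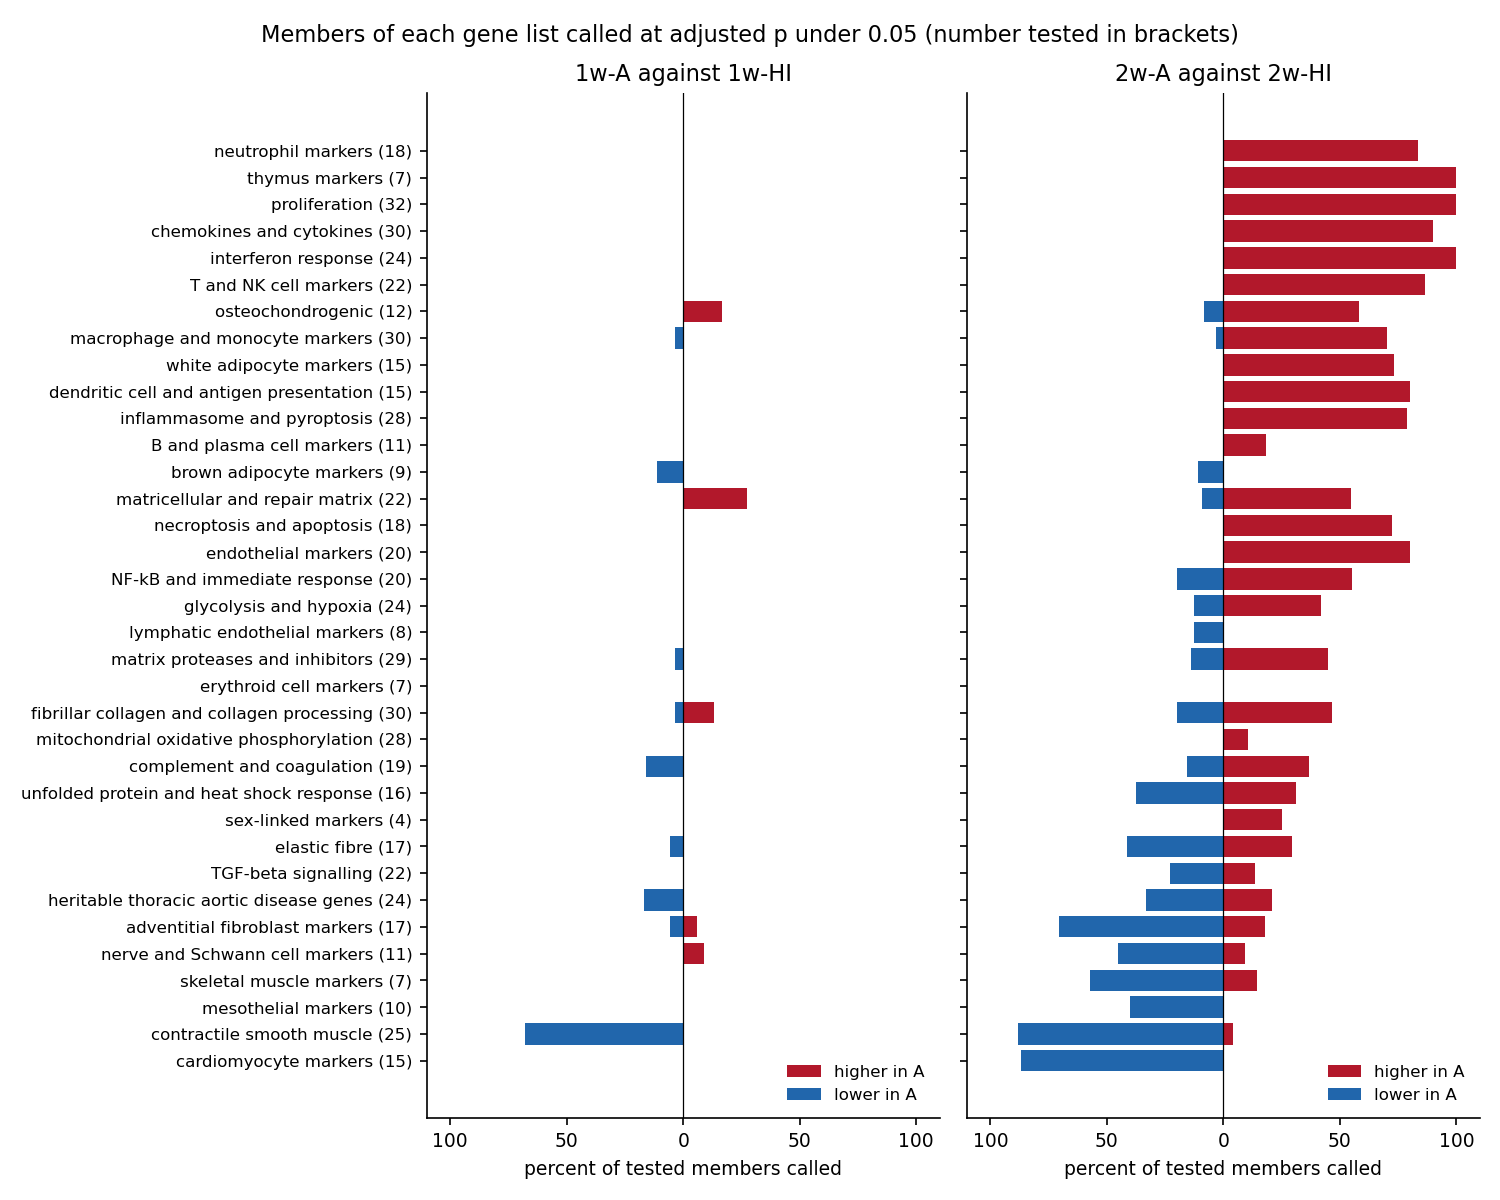
Percent of the tested members of each gene list called higher (right bars) or lower (left bars) in A than in HI, at 1w and at 2w, with the number tested in brackets. At 1w 17 of 25 contractile genes were lower, and at 2w all 32 proliferation and all 24 interferon genes were higher.

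Whether the difference between the arms changed from day 7 to day 14 was tested directly, as the A against HI difference at 2w minus that at 1w, so an upward shift means that A moved up relative to HI. Proliferation showed the clearest change. Of its 32 genes 31 shifted upward and 0 downward: Kif20a by 2.58 ± 0.32 log2 units (SE, adjusted p = 5.6e-05) and Tk1 by 1.88 ± 0.28. The libraries highest in thymus genes in their groups, 1w-HI replicate 1 and 2w-A replicate 4, were also highest in proliferation genes (means of 5.14 and 5.37 log2 CPM). All 32 still rose at 2w without 2w-A replicate 4. That covers the 2w difference only, and the count of shifted proliferation genes without these libraries is not given here. Outside the list the mitotic genes Prc1 (2.30 ± 0.28), Ckap2l (2.59 ± 0.38), Spc24 (2.63 ± 0.39) and Dlgap5 (2.82 ± 0.42) shifted upward with 6 of 6 2w-A libraries above 2w-HI. Mmp13 shifted upward by 5.99 ± 0.97 (adjusted p = 0.000957), Il6, a cytokine gene, by 5.83 ± 1.17 (adjusted p = 0.00437) and Fcgr1 by 2.59 ± 0.49. Nlrp3 shifted upward by 3.81 ± 1.02 (adjusted p = 0.024, 6 of 6) and Il1b by 5.08 ± 1.34 (adjusted p = 0.0214, 5 of 6). These sizes depend on the batch term: without it Mmp13 stood at 7.81, Il6 at 7.05, Nlrp3 at 5.10 and Il1b at 6.84, and 2254 genes passed. The difference did not pass for Gsdmd (0.59 ± 0.26, adjusted p = 0.147), Casp1 (0.81 ± 0.36, adjusted p = 0.161), Casp4 (0.99 ± 0.35, adjusted p = 0.0719) or Il18 (0.91 ± 0.36, adjusted p = 0.108). Without the batch term Casp4 (1.28, adjusted p = 0.0113) and Il18 (1.07, adjusted p = 0.0277) passed, so for these 2 genes the outcome rests on that term. Among the genes that shifted downward were the cardiac actin gene Actc1 (-8.28 ± 1.52), the intermediate filament gene Des (-2.13 ± 0.41), the bicarbonate transporter gene Slc4a10 (-2.85 ± 0.55), Tmem64 (-1.07 ± 0.19), the matrilin gene Matn2 (-0.93 ± 0.18) and Igfbp6 (-1.72 ± 0.35). Contractile genes shifted down in 2 of 25, and chemokines upward in 14 of 30 and down in 1. Inflammasome genes shifted upward in 7 of 28 (20 adjusted over the list alone). In total 790 genes shifted upward and 228 downward, but 262 passed without 1w-HI replicate 1 and 2w-A replicate 1, and the inflammasome count was then 1.

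Against the baseline, 1w-A differed in 4518 genes higher and 4173 lower, both groups in batch 1. Contractile genes were lower in 1w-A, and matrix, macrophage and mitotic genes higher. Myh11 fell from 14980 ± 2072 CPM (SD, n = 6) to 1016, a log2 fold change of -3.88 ± 0.38 (SE, adjusted p = 8.46e-10, lower in 6 of 6), and Synpo2 (-3.86 ± 0.35), Mylk (-2.95 ± 0.27) and Lmod1 (-3.28 ± 0.32) with it. Contractile genes fell in 23 of 25 and rose in 1. Col3a1 and Col1a1, the main fibrillar collagens, rose from 10080 ± 1452 and 5196 ± 662 CPM to 60540 ± 8661 and 41690 ± 7343 (log2 fold changes 2.59 ± 0.18 and 3.00 ± 0.23, 6 of 6 each), the crosslinking enzyme gene Lox rose by 3.26 ± 0.22, and collagen genes rose in 26 of 30 and fell in 1. Macrophage genes rose in 26 of 30 and fell in 1, with the lipid receptor gene Trem2 at 4.90 ± 0.35, C1qa at 3.87 ± 0.26 and C1qc at 3.77 ± 0.27. Proliferation genes rose in 31 of 32 and fell in 1 (Cdk1 4.90 ± 0.31, Tk1 4.15 ± 0.23). Neutrophil genes rose in 18 of 18, endothelial genes in 20 of 20, interferon genes in 23 of 24 (Oas1a 5.23 ± 0.40) and complement genes in 15 of 19 with 3 falls, C4b rising by 3.19 ± 0.14. Inflammasome genes rose in 22 of 28 and fell in 2: Gsdmd by 2.28 ± 0.19 (adjusted p = 3.79e-11), Casp1 by 3.52 ± 0.29, Casp4 by 1.90 ± 0.25, Nlrp3 by 4.93 ± 0.97, Il1b by 6.30 ± 1.29 and Il18 by 2.28 ± 0.26, each in 6 of 6. The largest rises were the granule gene Ltf (9.42 ± 1.93) and Bpifb1 (8.83 ± 1.89), both highest in 1w-A replicate 6, the scavenger receptor gene Marco (7.76 ± 0.91) and Nxpe5 (7.15 ± 0.73). The largest falls included Tcap (-5.61 ± 0.56), Vwc2 (-4.97 ± 0.50) and the olfactory receptor gene Olfr224 (-4.95 ± 0.56).

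In 1w-HI the same comparison with the baseline found 3762 genes higher and 3009 lower. With the batch term, the log2 fold changes rest on the 4 1w-HI libraries of batch 1, while the CPM means cover all 7. Contractile genes fell in 22 of 25, with Cald1 at -1.26 ± 0.19 log2 units (SE), Tpm1 at -1.46 ± 0.24, Mylk at -1.66 ± 0.30 and Ldb3 at -1.72 ± 0.31, each lower in 7 of 7 libraries. Collagen genes rose in 22 of 30 and fell in 1 (Lox 2.64 ± 0.22, Col3a1 2.19 ± 0.19, the proline hydroxylase gene P4ha3 5.02 ± 0.47). Macrophage genes rose in 26 of 30 and fell in 1 (Trem2 4.90 ± 0.37, C1qa 3.46 ± 0.27, C1qc 3.47 ± 0.28), proliferation genes in 31 of 32 (Cdk1 4.64 ± 0.32, Tk1 3.93 ± 0.24), T and NK cell genes in 22 of 22 and neutrophil genes in 17 of 18. Oas1a rose by 4.38 ± 0.41. Inflammasome genes rose in 24 of 28 and fell in 2: Gsdmd by 2.29 ± 0.20 (adjusted p = 3.12e-10), Casp1 by 3.43 ± 0.30, Casp4 by 2.15 ± 0.27, Nlrp3 by 5.03 ± 1.01, Il1b by 6.85 ± 1.33 and Il18 by 2.08 ± 0.28, each in 7 of 7. Without the batch term, which this comparison also needs, Nlrp3 stood at 6.32 and Il1b at 8.61. The acute-phase gene Saa3 rose from 6.99 ± 10.5 to 2680 ± 1323 CPM and Arg1 from 0.574 ± 0.594 to 558 ± 562 (log2 fold changes 8.16 ± 1.34 and 8.59 ± 1.96, 7 of 7 each, with Arg1 at 9.92 without the batch term). The formyl peptide receptor gene Fpr2 and Saa2 had 0 reads in B and were at least 167-fold and 111.3-fold higher against a floor of 3 reads over the group. Ren1, the renin gene (-3.80 ± 0.54), and the neuronal genes Gria1 (-2.74 ± 0.43) and Dpp10 (-2.58 ± 0.69) fell in 7 of 7. Tg, thyroglobulin, was called lower (-3.02 ± 1.06, adjusted p = 0.0185) although 7 of 7 libraries lay above the B median, because B replicate 2 held 151 CPM against a mean of 1.27 in the other 5.

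Each 2w group and B lie in different batches, so the log2 fold changes below are those of the fit without a batch term. In 2w-A the contractile genes Actg2 (-2.99, 60.4 ± 21.8 CPM, n = 6, against 479 in B), Des (-2.77), Synpo2 (-3.31) and Mylk (-2.67) stood below B, while Lox (2.89), Col8a1 (5.32), C1qa (3.74), Trem2 (4.91), Tk1 (3.99), Cdk1 (4.60) and Oas1a (5.49) stood above it, each in 6 of 6 libraries. Col10a1 (7.31), Krt17 (5.35), Krt5 (6.35) and Prss16 (7.10) were the largest rises, and Gria1 (-4.64), Vwc2 (-4.40), Bex4 (-4.06) and Ppp1r1b (-4.46) the largest falls, of the fit with the batch term, and without it Il1b rose more than any of these 4. With the batch term 3113 genes rose and 2293 fell, and without it 8520 were called, 5207 of them shared. With the term, 21 of 25 contractile genes fell and 0 rose, 16 of 30 collagen genes rose and 1 fell, 25 of 30 macrophage genes rose and 2 fell, and 31 of 32 proliferation, 24 of 24 interferon and 21 of 28 inflammasome genes rose. Neutrophil genes rose in 9 of 18 with it and in 18 without it. Gsdmd rose by 2.26 ± 0.30 with the term (SE, adjusted p = 1.46e-06, 6 of 6) and by 2.40 without it, and Casp1 by 3.62 and 3.69, Casp4 by 1.55 and 2.15, Nlrp3 by 4.50 and 6.63, Il1b by 5.92 and 8.63 and Il18 by 2.05 and 2.40.

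The 2w-HI group stood nearer to B. The largest rises and falls named were those of the fit with the batch term. The proton pump gene Atp6v0d2 stood at 39.6 ± 19.4 CPM (SD, n = 7) against 0.167 in B and the elastase gene Mmp12 at 642 ± 356 against 3.75 (log2 fold changes 7.83 and 7.43 without a batch term, 7 of 7 each). H2-M2, a class I gene with close relatives, rose by 5.76, and the coagulation gene F7, with 3 reads in B, stood 172-fold higher (95% counting interval 58.6 to 837). Trem2 (4.65), Gpnmb (4.41), H2-Ab1 (3.53), Lox (2.30), Col3a1 (1.82), Cthrc1 (5.18), Dpt (1.92), Tk1 (1.89) and Cdk1 (2.27) rose in 7 of 7. The resident macrophage genes Fcna (-2.39) and Cd163 (-1.93), the clock gene Cry1 (-1.46) and Mybpc2 (-0.82, adjusted p = 0.067 without a batch term and 0.0245 with it) were the largest falls with the term. With it 1231 genes rose and 359 fell, and without it 4853 were called, 1513 of them shared. The batch term decided several lists. With it 0 of 25 contractile genes fell (Cald1 -0.56 ± 0.27, adjusted p = 0.195, and -0.71, adjusted p = 0.000719 without it), 8 of 28 inflammasome, 15 of 32 proliferation, 9 of 30 chemokine, 11 of 24 interferon and 1 of 20 endothelial genes rose. Without it the counts were 13, 20, 25, 24, 18 and 16. Collagen genes rose in 14 of 30 and macrophage genes in 17 of 30 with the term. Gsdmd rose by 1.68 ± 0.29 (SE, adjusted p = 0.000279, 7 of 7) with the term and by 1.82 without it, and Casp1 by 2.72 and 2.79. Casp4 (0.81 ± 0.39, adjusted p = 0.195), Nlrp3 (0.79 ± 1.36, adjusted p = 0.774), Il1b (1.39 ± 1.79, adjusted p = 0.686) and Il18 (0.94 ± 0.41, adjusted p = 0.14) did not pass with the term, though 7 of 7 libraries lay above the B median. All 4 passed without it, at 1.41, 2.92, 4.10 and 1.30 (adjusted p = 6.72e-05, 0.0381, 0.0185 and 0.000253), so their calls rest on that term.

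Within the A arm, hardly any gene could be called between day 14 and day 7, which lie in different batches. In simulated data this comparison recovered 19.4% of the genes changed 1.5-fold and 46.3% of those changed 2-fold. The lack of calls therefore does not show that the times were alike. Myh11 stood at 1401 CPM in 2w-A and 1016 in 1w-A and Gsdmd at a log2 fold change of -0.02 ± 0.29 (SE, adjusted p = 0.992, 3 libraries higher and 3 lower). A single gene was called, Igkv3-12, an immunoglobulin light chain gene of a family with near-identical copies, which was named after its values were seen. It stood at 0.251 CPM in 2w-A and 2.90 in 1w-A (adjusted p = 0.00447, lower in 6 of 6), but at an adjusted p of 0.162 without a batch term. With edgeR 0 genes rose and 1 fell, against 1144 at an unadjusted p under 0.05 and 10 with DESeq2. Without a batch term 49 genes were called, and Igkv3-12 was not among them. With the term all 35 lists had 0 members past the threshold over all genes, and without it 3 collagen, 1 matricellular, 2 cardiomyocyte and 2 nerve genes were lower and 1 chemokine gene higher. Adjusted over the list alone with the batch term, 8 of 11 B and plasma cell genes stood lower, 6 of 7 thymus and 7 of 9 brown adipocyte genes higher, and 4 of 10 mesothelial and 5 of 16 unfolded protein genes lower. Without the term the median log2 fold change went from -2.78 to -0.14 for the B and plasma cell list, from 5.04 to 1.55 for thymus, from 3.64 to -0.09 for brown adipocytes, from -1.94 to -0.90 for mesothelium and from -0.48 to -0.12 for unfolded protein genes, so these counts rest on the batch term.

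Within the HI arm, day 14 differed from day 7 in 1727 genes higher and 2322 lower. With the batch term, the log2 fold changes compare 2w-HI with the 3 1w-HI libraries of batch 2, while the CPM means cover all 7. Inflammatory and mitotic genes fell. Il6 fell from 35.9 ± 27.9 CPM (SD, n = 7) to 0.657 ± 0.371 (n = 7), a log2 fold change of -6.57 ± 0.94 (SE, adjusted p = 2.64e-05, lower in 7 of 7), Lcn2 from 653 ± 402 to 17.5 ± 8.10 (-5.80 ± 0.96), Mmp13 by 6.30 ± 0.77, Cxcl13 by 4.79 ± 0.66 and Mmp8 by 6.06 ± 1.08. Arg1 (-8.09 ± 1.66), the granule gene Ngp (-7.33 ± 1.34) and Cxcl3 (-6.98 ± 1.26) were the largest falls, with U90926, which at 1 read in 2w-HI was 384-fold lower (95% counting interval 68.6 to 15210). Neutrophil genes fell in 17 of 18, chemokines in 24 of 30 with 1 rise, inflammasome genes in 20 of 28 with 1 rise and proliferation genes in 30 of 32 (Kif20a -2.64 ± 0.26, Cdk1 -2.41 ± 0.28, Tk1 -2.12 ± 0.22). B and plasma cell genes fell in 10 of 11, endothelial genes in 12 of 20 and macrophage genes in 19 of 30 with 1 rise, Gpnmb (2.82 ± 0.48). Matricellular genes fell in 7 of 22 and rose in 1, with Thbs1 at -3.66 ± 0.46 and the protease inhibitor gene Timp1 at -3.33 ± 0.44, and proteases and inhibitors fell in 11 of 29 and rose in 4. Contractile genes rose in 14 of 25 (23 adjusted over the list alone), with Tpm1 at 0.94 ± 0.26, Cald1 at 0.70 ± 0.20 and Mylk at 1.07 ± 0.32, and adventitial genes in 7 of 17, with Gsn at 1.85 ± 0.25 and Serpinf1 at 0.97 ± 0.17. Gsdmd fell by 0.61 ± 0.20 (adjusted p = 0.0243), Casp4 by 1.34 ± 0.27, Nlrp3 by 4.24 ± 0.79, Il1b by 5.46 ± 1.06 and Il18 by 1.13 ± 0.28, each lower in 7 of 7, while Casp1 passed only without the batch term (-0.71 ± 0.29, adjusted p = 0.0638 with it, and -0.67, adjusted p = 0.0237 without it). Without the term the falls of Arg1 (-7.24), Ngp (-6.21), Cxcl3 (-5.91), Il6 (-5.75), Mmp13 (-5.34), Mmp8 (-5.02), Cxcl13 (-3.80), Nlrp3 (-3.40) and Il1b (-4.51) were smaller, as was the rise of Gpnmb (2.15). The rises of Myh6 (5.33 ± 1.88) and Myl7 (4.80 ± 1.43) were highest in 2w-HI replicate 6 and stood at 3.15 and 3.12 without a batch term. Cidea, a lipid droplet gene of adipocytes, and Slc27a2 were called higher (4.29 ± 1.01 and 5.22 ± 1.52), but stood at 0.11 and 0.24 without it.

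Junction usage within genes was compared between A and HI at each time to ask whether splicing differed beside expression. At 2w 130 of 10641 genes were called, led by Cald1, the caldesmon gene, whose junction from 34722951 to 34730377 on chromosome 6 was read 185 ± 37.8 times (SD, n = 6) in 2w-A and 69.7 ± 14.3 (n = 7) in 2w-HI (log2 relative usage 1.28, adjusted p = 5.72e-17). Actg1 (log2 relative usage -1.82), Actn1, an actin crosslinker (1.29), and Aldoa, a glycolytic enzyme (-1.05), followed. A Luc7l2 junction with a mean of 19.3 reads in 2w-A and 0 in every 2w-HI library is uncertain, since a junction read in some libraries and never in others can also reflect the alignment. At 1w 8 genes were called, against 93 at an unadjusted p under 0.05, among them Rps24, a ribosomal protein gene (-1.98), Ppp1r12a, the myosin phosphatase subunit (-1.40), Gnas (1.68) and the focal adhesion gene Vcl (-1.07). The Col3a1 junction from 45376500 to 45377117 on chromosome 1 was read in 4 of 6 1w-A libraries and in 0 of 7 1w-HI libraries and is uncertain for the same reason. So are the Rps24 junction, read in 2 of 6 1w-A and 4 of 7 1w-HI libraries, and the Gnas junction, read in 6 of 6 and 4 of 7.

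Cassette exons of contractile and cytoskeletal genes differed between the arms at both times. The 39-base exon of Myh11 was included in 30.1% ± 3.45 (SD, n = 6) in 1w-A against 42.2% ± 2.05 (n = 7) in 1w-HI, and in 34.9% ± 3.85 against 49.3% ± 1.83 at 2w, with 48.5% ± 1.21 in B. The 165-base exon of Smtn, smoothelin, stood at 59.7% against 26.6% at 1w and 51.6% against 15.2% at 2w. Of 2 exons of Tpm1, tropomyosin, that at 66955068 stood at 33.5% against 10.9% and 26.1% against 6.08%, and that at 66955406 at 35.8% against 69.1% and 44.7% against 82.4%. Exons of Flna (24 bases, 43.1% against 33.3% and 40.03% against 29.97%) and Map4 (222 bases, 95.03% against 91.3% and 94.7% against 84.3%) were included more in A. In fibronectin, the 270-base exon did not differ at 1w (21.1% against 21.1%) and stood at 18.1% against 11.03% at 2w. The 273-base exon stood at 24.5% ± 4.50 against 20.7% ± 5.08 at 1w, a gap smaller than either SD. At 2w it stood at 16.9% against 9.60%. Other exons that passed at both times lay in Cald1 (84 bases, 38.3% against 60.02% and 38.6% against 78.96%) and Pdlim7 (at 55656021, 79.4% against 61.7% and 77.3% against 53.1%), each in 1 of its events. With 2-sided exact permutation tests, 15 of 30 exon events passed at 1w and 21 of 31 at 2w after adjustment, and 13 of 31 at 1w within batch 1 (an exon with other flanking junctions is another event), where the smallest p possible was 0.00952. The smallest p that these tests can give with 6 and 7 libraries is 0.00117.

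**Figure D5:**
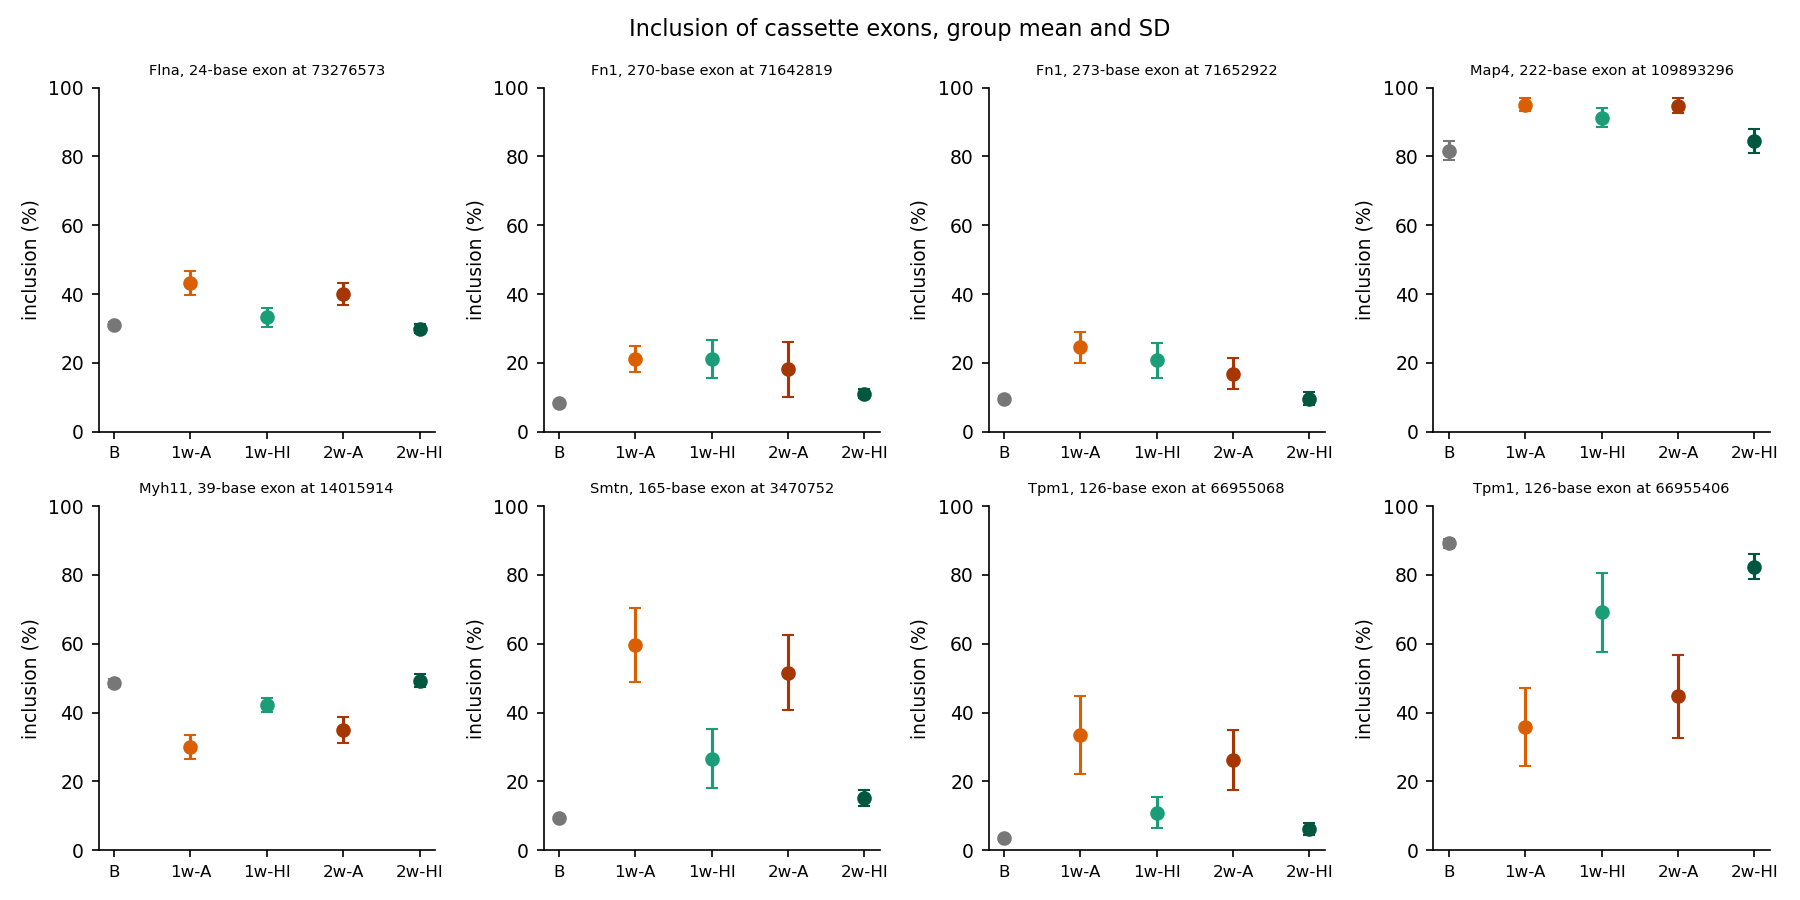
Inclusion in percent of 8 cassette exons, with a point at the mean and bars at the SD of each of the 5 groups. The 39-base exon of Myh11 stood at 48.5% in B, 30.1% in 1w-A and 49.3% in 2w-HI.

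Reads on junctions absent from the aligner's annotation made up 0.000448% ± 0.000107 (SD, n = 6) of the junction reads in 1w-A and 0.000401% ± 7.82e-05 (n = 7) in 1w-HI, 0.000512% ± 0.000116 in 2w-A and 0.000549% ± 0.000113 in 2w-HI, with 0.000553% ± 0.000118 in B. These were 33 to 85 reads per library, while the junctions that could not be named here held 1.17% of all unique reads. The aligner's flag marks hardly any of the latter, so it cannot tell whether unannotated splicing differed. In exact permutation tests the flagged share of A and HI did not differ at 1w (p = 0.43, and 0.495 within batch 1) or at 2w (p = 0.559).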

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

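The tests of exchanged labels, of leukocyte RNA, of the share of smooth muscle cells and of the split by batch, and the fits without the out-of-place libraries or without the libraries highest in thymus genes, were chosen only after the results were seen.

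In 2w-A replicate 1 inflammatory and glycolytic genes stood far above the rest of the group and matrix genes far below. Nlrp3 stood at 150.3 CPM and Il1b at 1654 CPM, the NF-kB list at a mean of 5.872 log2 CPM and the glycolysis list at 7.615, while the elastic fibre list stood at 8.03, the adventitial list at 6.615 and the osteochondrogenic list at 1.207. Thymus genes stood far above the rest of the group in 1w-HI replicate 1 (6.322) and 2w-A replicate 4 (6.456), which also detected 16530 genes, and the osteochondrogenic list in 1w-HI replicate 1 (3.799). In 1w-A replicate 6 the collagen list stood low (8.728), the glycolysis list high (6.889), the 10 most-read genes low (17.37% of reads) and the unannotated share high (0.0006602%). The remaining libraries far from their group were 2w-HI replicate 5 on the contractile list (7.577), 2w-HI replicate 1 on the NF-kB list (5.15), B replicate 4 on the collagen list (7.628) and for Casp4 (12.6 CPM), and B replicate 6 on the B cell list (0.7711). By chance about 1 in 20 groups holds such a library, and 20 were found in 230 groups tested.

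The difference between A and HI changed from 1w to 2w in 1018 genes by a test of the difference itself. Among those named, the mitotic genes Prc1 (2.3038 log2 units), Kif20a (2.5814), Ckap2l (2.5875), Spc24 (2.6298), Dlgap5 (2.8205) and Tk1 (1.8772), the inflammatory genes Il6 (5.8326), Fcgr1 (2.5899), Nlrp3 (3.8105) and Il1b (5.0831) and the collagenase gene Mmp13 (5.992) shifted upward in A. Tmem64 (-1.0676), Actc1 (-8.2846), Matn2 (-0.9311), Des (-2.1311), Slc4a10 (-2.8502) and Igfbp6 (-1.7211) shifted downward. These shifts rest partly on 2 libraries: 262 genes passed without 1w-HI replicate 1 and 2w-A replicate 1, and without the latter the 2w fold of Nlrp3 went from 3.71 to 1.48 log2 units and that of Il1b from 4.53 to 1.42. The share of junction reads that mapped to more than 1 place, a column not used in the comparisons, was above the 2.81% of B in 1w-A (3.34%), 1w-HI (3.475%), 2w-A (3.372%) and 2w-HI (3.151%).

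1w-HI replicate 1 and 2w-A replicate 1 lay nearer the centre of another group than of their own, as did 1w-HI replicate 3 (2w-A, 0.461 against 0.513), 2w-A replicate 2 (2w-HI, 0.651 against 0.750) and 2w-A replicate 4 (1w-A, 0.6228 against 0.6232). Whether their labels were exchanged cannot be told: 2w-A replicate 1 lay 1.303 times as far from the centre of 1w-HI as that group's own farthest library, but 1.506 times for its own group, and 1w-HI replicate 1 lay at 0.833 times for 2w-A and 1.282 times for its own. With 178 thymus and lymphoid genes left out, 0 of the 2 moved to their own group and 5 libraries in all were then nearest another group. The thymus score of 2w-A replicate 1 was not raised (1.92), so this tells nothing about that library. 1w-HI replicate 1 still lay nearest 2w-A (0.546 against 0.783 for its own group), so these genes alone did not place it there. Other genes of such tissue stayed in, so thymus or lymphoid tissue is not excluded for it. An exchange, a single wrong label and a more or less advanced lesion of the wall in these animals stay open. Without these 2 libraries, and with the other 3 kept, 1339 genes were called between 1w-A and 1w-HI.

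Contractile genes were lower in 2w-A than in 2w-HI. Dilution of the wall's RNA by leukocytes alone would lower endothelial genes alike. The endothelial and contractile medians however lay 2.54 log2 units apart, against 0.953 for the root of the summed squared SDs of both lists over their genes. A smaller share of smooth muscle cells alone would raise the endothelial and adventitial lists alike, and their medians lay 1.231 apart against 1.02 by the same measure. That measure holds the spread between genes and not between animals. Both tests were also set after the directions were seen, so the gaps carry no error rate. Whichever library was left out, the endothelial median stayed positive (0.515 to 0.806). The contractile and adventitial medians stayed negative (-2.13 to -1.71 and -0.674 to -0.471). These directions argue against either as the only change. They cannot exclude dilution or fewer muscle cells beside a change in endothelial cells or fibroblasts. Dilution, a changed share of cells and lower transcription of contractile genes in the muscle cells, alone or together, stay open. Lower transcription was not tested.

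Dbp and Per2 were lower in 1w-A than in 1w-HI. Collection of the groups at different times of day was tested on 11 other clock genes. Those of the same phase fell by a median of 1.41 log2 units, with 7 of 7 called (Tef, Hlf, Nr1d1, Per1, Per3, Ciart and Bhlhe41), and those of the opposite phase (Arntl, Npas2, Clock and Nfil3) stood at a median of 0.7802, with 0 of 4 called. The medians lay 2.19 apart, against 0.575 for the root of the summed squared SDs of both sets over their genes. A different time of day could give this, and so could a damped clock in 1w-A. Collection times are not in the labels, so the values cannot tell these apart. All 7 genes of the first phase stood lower in 1w-HI than in B as well. Their mean CPM was also lower in 2w-A than in 2w-HI, with Tef at 28.1 against 49.03 and Nr1d1 at 96.6 against 249.7. Of the opposite phase, Arntl, Clock and Nfil3 were higher in 2w-A and Npas2 lower. The lower means in A were thus not limited to day 7, but the 2 sets were not tested at 2w.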

How the results depend on the processing

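The fits without the 2 out-of-place libraries (1w-HI replicate 1 and 2w-A replicate 1), without the 3 libraries highest in thymus genes, and with only junctions read in both groups were chosen only after the data were seen. Of 4686 recomputed values of named genes, 4393 kept direction and side of the threshold, 255 lost their call (36 of them with only the groups compared and 33 with the replicate number as a block), 17 gained it and 21 changed sign. For 1w-A against 1w-HI, 297 genes passed with a 2-fold minimum, 1421 without a batch term, 271 with the most-read junction of each gene, 1.0e+02 with the replicate block (14 higher and 88 lower), 1339 without the 2 libraries and 16 to 1053 when each library was left out. Only 3 passed with only these groups fitted, where these groups alone set the spread. For 2w-A against 2w-HI, 2459 passed with the 2-fold minimum and 4409 with the most-read junction, and 6182 to 7285 when each library was left out. The 2-fold minimum left 3963 for 1w-A against B, 2965 for 1w-HI against B, 3342 for 2w-A against B, 968 for 2w-HI against B and 1570 for 2w-HI against 1w-HI, by construction. Without a batch term, 8520 passed for 2w-A against B, 4853 for 2w-HI against B, 49 for 2w-A against 1w-A and 2254 for the difference between times. The most-read junction, which holds fewer reads, gave 3473 for 2w-A against B, 892 for 2w-HI against B, 2379 for 2w-HI against 1w-HI and 312 for the difference between times. With only the groups compared, 5747 passed for 2w-HI against B, 0 for 2w-A against 1w-A and 610 for the difference between times. For the first 2 of these the batch cannot be fitted. With the replicate block, 0 passed for 2w-A against 1w-A, 2332 for 2w-HI against 1w-HI and 673 for the difference between times. The block is an alternative only, since the numbers do not pair the libraries, and it takes the title numbers of 2w-A, which differ by 1 from those of the library names. For 2w-A against 1w-A, 8 passed without the 2 libraries and 10 with DESeq2. The difference between times kept 262 without the 2 libraries and 487 without the 3. Lists called by camera fell to 0 and 0 with an estimated correlation, and fry called 0 at 1w. Usage at 1w was 3 genes with limma, 5 with at least 20 reads per junction, 15 without a batch term, 5 with the replicate block and 27 without the 2 libraries, and at 2w 216 with limma and 75 with at least 20 reads. The causes of these changes were not tested. Values near 0 changed sign. The unannotated share at 1w stood at -0.000663 percentage points with multi-mapped reads. The 270-base exon of Fn1 at 1w stood at 2.253 percentage points in batch 1 and 0.04872 with multi-mapped reads. The log2 fold change of Gsdmd at 1w was 0.0110 with RLE size factors, 0.0167 with multi-mapped reads, 0.0289 with only these groups and 0.0114 with DESeq2, and -0.0889 to 0.1636 when each library was left out. That of Casp1 at 1w was -0.0617 with the replicate block and -0.0299 to 0.2711 when each library was left out, and that of Nlrp3 -0.3158 to 0.1246. Nlrp3 in 2w-HI against B was -0.0933 with the most-read junction. Gsdmd in 2w-A against 1w-A was 0.1147 without a batch term, 0.0092 with the most-read junction, 0.0951 with the replicate block, 0.1603 without the 3 libraries and 0.1127 with only these groups. The counts of cassette exon events stayed within 13 to 15 at 1w and 18 to 21 at 2w. Gene counts with RLE size factors, no filter on low counts, multi-mapped reads or every junction within a gene stayed within 1.5 times those reported in every comparison. A fit within 1 batch was not run for 2w-A or 2w-HI against B, for 2w-A against 1w-A or for lists, usage and exons at 2w, which lie wholly in 1 batch or across both. In simulated data the share of genes changed 1.5-fold that was recovered was lowest across batches, at 19.4% for 2w-A against 1w-A. Recovery was not split by read count.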

Other observations

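Some lists not described above also moved. Against B, in 1w-A the T and NK cell list rose in 20 of 22 genes, antigen presentation in 14 of 15, chemokines in 27 of 30 with 1 fall, matricellular genes in 17 of 22, proteases and inhibitors in 21 of 29 with 4 falls and necroptosis genes in 14 of 18. In 2w-A against B the T and NK cell list rose in 22 of 22 with and without the batch term. From 1w to 2w the difference of A from HI shifted upward in 12 of 22 T and NK cell, 9 of 15 antigen presentation and 9 of 24 interferon genes, and downward in 9 of 15 cardiomyocyte and 5 of 17 adventitial genes. Without 1w-HI replicate 1 and 2w-A replicate 1 the T and NK cell count was 0 and the antigen presentation count 2. From 1w-HI to 2w-HI, 7 of 15 cardiomyocyte genes rose, and 7 of 9 brown adipocyte genes rose with the batch term but 1 without it. Between the batches of 1w-HI, edgeR called 0 genes, against 1158 at an unadjusted p under 0.05.

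The split of 1w-HI by batch was chosen as a test only after the results were seen. Calls were recounted over other splits of the same libraries into groups of the same sizes. For 1w-A against 1w-HI the real groups called 606 genes and were the only 1 of 100 splits to reach that count, with 431 in the highest other. For 2w-A against 2w-HI (6937 against 5532) and 1w-A against B (8691 against 6298) they were 1 of 100 as well. These 2 comparisons lie within 1 batch, so the splits drawn bound chance at 1 in 100. They do not address other differences between the groups. The real groups were also 1 of 100 for 1w-HI against B (6771 against 6119), 2w-A against B (5406 against 1422), 2w-HI against B (1590 against 20) and 2w-HI against 1w-HI (4049 against 3086). In these and in 1w-A against 1w-HI, other splits mix the batches differently from the real groups, so the count alone does not exclude chance. For 2w-A and 2w-HI against B the real split is also the split by batch. The difference between times was reached by 2 of 100 splits (1018, highest other 1151). For junction usage at 2w the real groups were 1 of 40 (130 against 18). Chance was not excluded for 2w-A against 1w-A, where 20 of 100 splits called at least the real 1 gene and the highest called 1453, or for usage at 1w, where 2 of 40 reached the real 8 and the highest other called 8. For the batches of 1w-HI the count of splits says nothing about chance, since the real count was 0, which 35 of 35 splits reach by definition (highest other 686). A split that calls many times the real count points to a structure of the samples other than the groups compared. For the lists called by camera chance was not excluded at either time: 53 of 100 splits reached the real 13 at 1w and 68 of 100 the real 14 at 2w, with 25 and 23 in the highest others. The list calls of camera therefore carry no weight here, and the member counts rest on the tests of single genes.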
